A study of Homo sapiens with 2 samples.

How the data were processed

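Human prostate cells were measured with droplet single-cell RNA sequencing (10x Genomics 3' chemistry, version 3) in 2 libraries, 1 labelled prostate and 1 labelled verumontanum. Per the labels' protocols, tissue was digested with collagenase at 5 mg/mL for 4 h, 17400 cells were loaded, and reads were 150 bases long. The authors deposited a matrix of raw UMI counts per gene and barcode for each library, made with Cell Ranger 4.0.0 on GRCh38, per the submitters' processing notes. The annotation release behind the counts was not given in the sources used here. The files held 36601 genes, of which 34616 had a position in GENCODE 29, from which coordinates were taken. Depth was 29894654 UMIs over 2719 prostate barcodes and 66601948 UMIs over 5428 verumontanum barcodes.

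Filters, cell type markers, 24 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Barcodes with fewer than 200 genes (217 and 715) or more than 20% of counts from mitochondrial genes (18.8% and 18.4% of barcodes) were left out, and Scrublet, run per library in scanpy with an expected doublet rate of 0.06, called 5 prostate and 108 verumontanum doublets at its own thresholds of 0.384 and 0.243, which were removed. Doublets of like cells are not found this way. The remaining 2195 and 4320 cells were clustered together without integration: 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1, seed 1. A cluster was named after the cell type with the most markers among its top 10 genes by fold, ties going to the type with more detected markers, if it had at least 4 of these, where detected means a UMI in at least 25% of its cells and a level at least 2-fold above the other cells. It stayed unnamed or mixed where a tied type, or a type of another lineage, had more than 0.5 times as many. Clusters 15 and 17 had no marker among their top 10 genes and were named endothelial-like by 16 and 10 detected markers. Names are given as likeness to a type (luminal-like), since no protein or position was measured.

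Shares of cells have exact Clopper-Pearson intervals, and the limit given for a share of 0 is 3 counts over the total. Within each class with at least 30 cells in each library, UMIs were summed over cells, scaled to CPM of the class total, and compared as verumontanum over prostate with an exact conditional 95% interval; CPM carry exact Poisson intervals. A count of 0 was set to a floor of 3 counts, so such a fold is a lower bound. Genes were named per class and direction as the 10 whose interval bound nearest to 1 was farthest from 1, among those with at least 50 UMIs in the higher library, at least 2-fold, and at least 10% of the gene's highest class level there. Some of these are printed, with 2 to 4 members per list by the same bound; members that ran against the rest of a list were added after the data were seen. Mitochondrial, ribosomal protein, immunoglobulin and T cell receptor segment genes and genes tied to sex were never named. A list's median covers members with at least 10 UMIs, with a 95% range from 1000 Poisson redraws and a percentile among 10000 random lists of equal size matched in 20 expression bins, which describes these libraries only. Members with 0 UMIs in 1 library were left out where the floor stood at or above the other library's level. With at least 10 UMIs, this can remove only members seen in the library with the larger class total. ACP3 is ACPP and TMEPAI is PMEPA1 in these files. Shares of cells with a UMI were also computed after each cell was thinned to 1000 UMIs, which left out 237 prostate and 120 verumontanum cells with fewer.

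The scripts were tested on simulated data drawn from the mean of the prostate library at 10% of the UMIs of each library, with 14745 genes and 50 genes per fold. Median estimated ratios were 0.253, 0.504, 2.00 and 3.95 for true ratios of 0.25, 0.5, 2 and 4, and 94%, 98%, 96% and 92% of intervals held the true ratio; for unchanged genes it was 96.0%.

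Alternatives covered the mitochondrial limit, no filter, a minimum of 500 genes, doublets kept, other clustering resolutions, 4000 variable genes, separate clustering, TMM (edgeR) and DESeq2 scaling, totals without mitochondrial and ribosomal protein genes, means of per-cell CPM, thinning, and other minimums for list members. A doublet score above 0.25 in both libraries, at least 3 detected markers, and clusters with at least 30 cells of each library were added after the data were seen. No p-value was computed, because each group had 1 library. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Classes with fewer than 30 cells in a library (luminal-, umbrella-, glia-, mast- and lymphatic-like) were not compared gene by gene.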

Results

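Single cells from normal human prostate were profiled by droplet RNA sequencing in 2 libraries, 1 from prostate tissue (the peripheral zone, per the series title) and 1 from the verumontanum, the ridge in the wall of the prostatic urethra where the ejaculatory ducts open. The comparison asks how cell types and their gene expression differed between these regions. The deposited tables held 2719 barcodes with 29894654 unique molecular identifiers (UMIs, a count of captured RNA molecules) for prostate and 5428 barcodes with 66601948 UMIs for verumontanum. After filtering, 2195 prostate cells (median 6586 UMIs and 2018 genes per cell) and 4320 verumontanum cells (median 8479 UMIs and 2219.5 genes) were kept. Epithelial cells held a median of 2039.5 UMIs and 914 genes in prostate and 17127 UMIs and 3085 genes in verumontanum. Thinned to 1000 UMIs, they held a median of 555 and 495 genes, with 127 of 404 and 42 of 1998 cells left out for lower depth. Each region had 1 library and so no replicates: region cannot be told apart from donor or handling, no test was run, and all intervals are 95% intervals that cover counting error only. Ratios are verumontanum over prostate throughout, and levels are CPM, the UMIs of a gene scaled to an equal total in each library's cells of a class, with pairs of levels given as prostate, then verumontanum.

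Epithelial classes differed between the libraries. Glandular luminal-like cells, which make the prostatic secretion, were 13.1% of kept prostate cells (287 of 2195, exact Clopper-Pearson interval 11.7 to 14.6%) and 1 cell of 4320 in verumontanum (0.0231%). This class joined 2 clusters of unlike depth. Cluster 18 (138 prostate cells) had a median of 26963.5 UMIs and 10 luminal markers among its top 10 genes. Cluster 16 (149 prostate cells) had a median of 929.5 UMIs and 1 such marker. With each library clustered by itself, 140 of 2195 prostate cells took the luminal-like name. Umbrella-like cells, the surface layer of the urinary tract lining, were 5.97% (5.28 to 6.72%) of verumontanum cells and 0 of 2195 prostate cells, which allows a share of up to 0.137% by the rule of 3 counts over the total (exact upper bound 0.168%). Basal-like cells, named for the layer on the basement membrane, made up 5.24% (4.34 to 6.26%) of prostate and 14.1% (13.1 to 15.2%) of verumontanum cells. Those of each library lay almost wholly in separate clusters with different keratins, so the shared name may cover different cell types. Glia-like cells of peripheral nerve were 9.11% (7.94 to 10.4%) and 0.671% (0.450 to 0.963%).

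All epithelial cells together were 18.4% (16.8 to 20.1%) of the prostate library and 46.2% (44.8 to 47.8%) of the verumontanum library. That verumontanum share was 27.2% with a mitochondrial limit of 10% and 25.0% with each library clustered by itself. Among epithelial cells, basal-like cells were 28.5% in prostate and 30.6% in verumontanum. In verumontanum, 56.5% of epithelial cells lay in clusters that no single type could name, against 0.495% in prostate. Cluster 1, with 736 verumontanum cells, had 6 markers of hillock cells (a squamous-like type), among them KRT13, LYPD3 and LY6D, beside 4 basal markers, and cluster 3, with 392 verumontanum cells, had 3 hillock markers. No cluster took the name of club- or hillock-like cells, types described in the proximal prostate and urethra. The share was thus 0 of 404 prostate and 0 of 1998 verumontanum epithelial cells. By the same rule, counting alone allows up to 0.743% (exact upper bound 0.909%) and 0.150% (0.184%). These bounds do not limit the true share, since the 0 follows from how clusters were named. In 6 alternative settings a verumontanum cluster took the hillock name, with shares from 17.8% to 47.6% of epithelial cells.

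Outside the epithelium, endothelial-like cells of blood vessels were 29.2% (27.3 to 31.2%) of prostate and 19.8% (18.6 to 21.0%) of verumontanum cells. Mural-like cells, the smooth muscle and pericytes around vessels and glands, were 18.8% (17.2 to 20.5%) and 10.8% (9.92 to 11.8%). Fibroblast-like cells were 5.60% (4.68 to 6.65%) and 11.4% (10.5 to 12.4%). T or NK-like lymphocytes were 3.78% (3.02 to 4.67%) and 6.11% (5.42 to 6.87%), and myeloid-like cells were 4.10% (3.31 to 5.02%) and 2.27% (1.85 to 2.76%). Of the 28 clusters, clusters 21 and 24 carried endothelial and mural markers at once and stayed apart as mixed. Together they held 4.92% of prostate and 0.764% of verumontanum cells. Their median depths were 23183 and 20255.5 UMIs, against 8693 in prostate endothelial-like and 7231 in prostate mural-like cells. Doublets that were not called could give such clusters, which was not tested. A cluster mostly of 1 library may be that library rather than a cell type. Digestion and loading can also shape these shares, which was not tested.

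**Figure D1:**
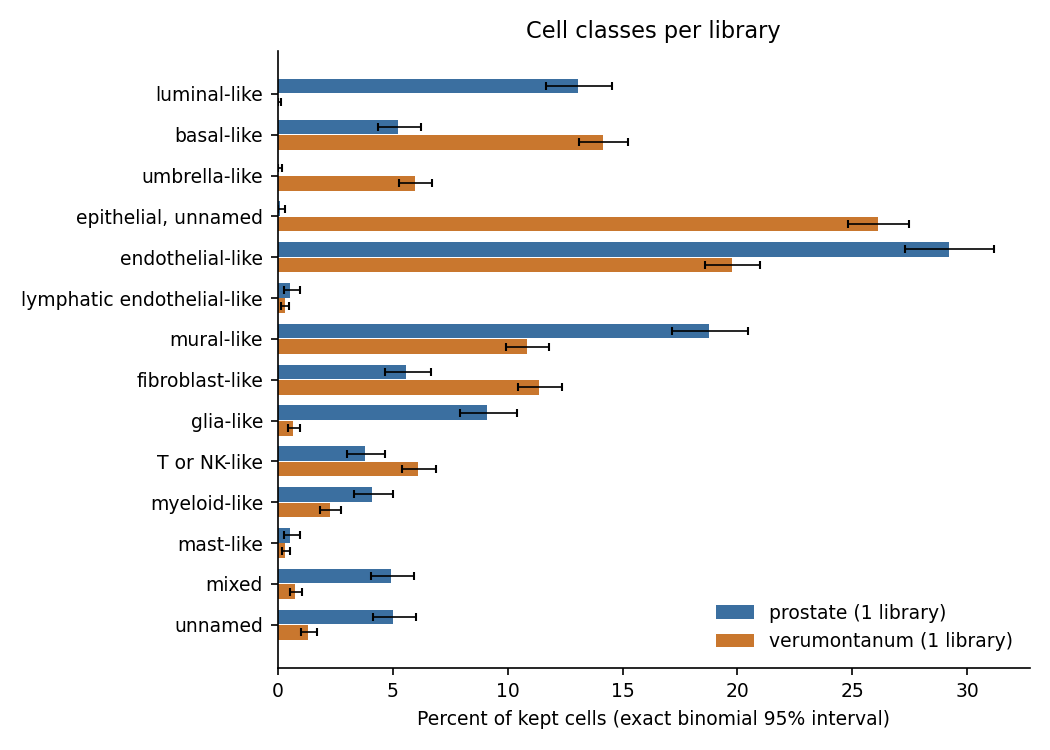
Share of kept cells (bars, percent, x axis) in each cell class (y axis) for the prostate and verumontanum libraries, 1 library each, with exact 95% intervals for counting error. Luminal-like cells stand at 13.1% and 0.0231%, and umbrella-like cells at 0 and 5.97%.

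Genes of the prostate gland were abundant in prostate epithelium and close to zero counts in verumontanum epithelium. KLK3 (prostate-specific antigen; ENSG00000142515, GRCh38 chromosome 19, 50854915 to 50860764) stood at 12865 (12788 to 12942) CPM in prostate epithelial cells and had 0 UMIs in those of verumontanum, at least 199476-fold lower. MSMB, a protein of seminal fluid, measured 14135 (14054 to 14215) CPM in the prostate library and 1.91 (1.54 to 2.35) CPM in the verumontanum library. ACPP, prostatic acid phosphatase, measured 12445 (12369.7 to 12521) CPM in the prostate library and 0.236 (0.118 to 0.423) CPM in the verumontanum library. HOXB13, the homeobox gene of the posterior body axis and prostate (ENSG00000159184, chromosome 17, 48724763 to 48729178), stood at 172 (163 to 181) CPM in prostate with 0 UMIs in verumontanum, at least 2667-fold lower. KLK2, which shares close sequence with KLK3, and the neuropeptide NPY were at least 66635-fold and at least 17079-fold lower. Over all deposited verumontanum barcodes KLK3 had 1 UMI and HOXB13 had 0.

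Among the genes that stood highest in verumontanum epithelium relative to prostate, the chemokine CCL20 measured 1.31 (0.656 to 2.35) CPM in the prostate library and 2208 (2194 to 2221) CPM in the verumontanum library. The aldo-keto reductases AKR1C2 and AKR1C1, which reduce steroids and reactive carbonyls and are hard to tell apart by sequence, stood at 1.55 and 2001 CPM and 2.63 and 1772 CPM in prostate and verumontanum. The collagenase MMP1 measured 0.955 and 634 CPM, and the cytokine gene IL1A 0.955 and 489 CPM. CYP1A1, a target of the aryl hydrocarbon receptor, had 0 UMIs in prostate and 235 (231 to 239.8) CPM in verumontanum, at least 657-fold higher, and the annexin ANXA10 was at least 397-fold higher. The list of inflammatory genes induced by the transcription factor NF-kB had 4 of 15 members at least 2-fold higher, 4 lower and 7 between, with a median log2 ratio of 0.52 (95% range 0.43 to 0.54).

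By list, 20 of 23 androgen-regulated prostate genes were at least 2-fold lower in verumontanum epithelium, 2 were higher and 1 lay between, with a median log2 ratio of -5.43 (95% range -5.53 to -5.35). HPGD, which degrades prostaglandins, was higher at 17.1 and 834 CPM. Of 12 prostatic fluid proteins, 11 were lower and 1 was higher, the trypsin inhibitor SPINK1 (13.1 and 2311 CPM), and the median was -9.12 (95% range -9.39 to -8.89). All 8 metallothioneins, the metal-binding proteins, were lower, with a median of -7.32 (95% range -7.48 to -6.35). MT1G stood at 491 and 0.15 CPM and MT1E at 577 and 0.559 CPM, though the MT1 genes resemble each other too closely for exact assignment. Among 12 stratified squamous genes, 8 were higher, 2 lower and 2 between, with a median of 3.06 (95% range 2.58 to 3.58). LY6D measured 18.9 and 1483 CPM, the keratin KRT13 25.2 and 1654 CPM, and the cornified envelope gene IVL had a ratio of 249.8 (44.8 to 9873) on 1 prostate UMI.

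Of 18 club secretory and mucosal defence genes, 8 were higher, 8 lower and 2 between. PSCA (10.1 and 992 CPM) and S100P (44.3 and 3753 CPM) stood higher in verumontanum, and TFF3 (139 and 1.03 CPM), TSPAN8 (156 and 6.26 CPM) and SCGB1A1 (8.6 and 0.129 CPM) stood lower. SCGB1A1 rested on few cells: 1.39% of luminal-like and 2.61% of basal-like prostate cells, and 1 verumontanum barcode with 6 UMIs. The median of the 18 genes was 0.41 (95% range 0.30 to 0.53), and its sign depended on settings: it was -0.51 when members needed only 1 UMI and 2.33 with a mitochondrial limit of 10%. The median of all genes in epithelium was -0.67, and TMM scaling added 0.92 to every epithelial log2 ratio. Ratios over all epithelial cells also follow the mix of classes: luminal-like cells were 71.0% of prostate and 0.0501% of verumontanum epithelial cells. Since UMIs were summed, each class weighs by its UMIs. Luminal-like cells held 7131542 of the 8376545 UMIs of prostate epithelial cells.

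**Figure D2:**
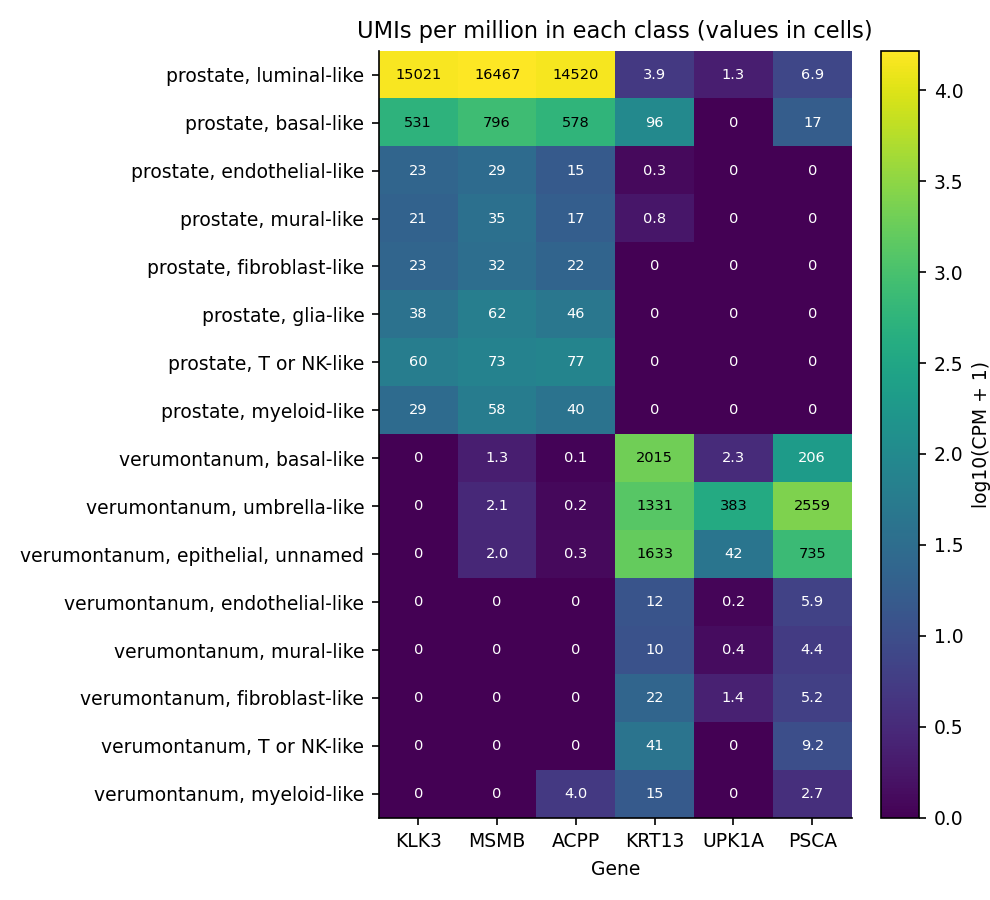
Level (CPM, printed in each cell, with colour for the log10 of CPM plus 1) of 6 marker genes (x axis) in the cell classes of each library (y axis), 1 library per region. KLK3 stands at 15021 CPM in prostate luminal-like cells and at 0 in every verumontanum class drawn, and KRT13 at 2015 CPM in verumontanum basal-like cells.

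HOX genes, which mark position along the body axis, stood higher or lower in subsets that were picked after the data were seen. All 7 measured genes of paralogue groups 10 to 13, the posterior end, were at least 2-fold lower in verumontanum epithelium, with a median log2 ratio of -7.17. Those of the HOXB cluster from HOXB2 to HOXB9 were all higher, 8 of 8, with a median of 4.61. HOXB2 measured 1.91 (1.09 to 3.1) CPM in the prostate library and 32.1 (30.5 to 33.8) CPM in the verumontanum library. HOXB6 had a ratio of 138 (24.7 to 5455) on 1 prostate UMI, and HOXA13 one of 0.00155 (0.000187 to 0.00567) on 2 verumontanum UMIs. Of the remaining 7 measured, 2 were higher, 3 lower and 2 between. Over all 22 HOX genes, 10 were higher, 10 lower and 2 between, the median was -0.20 (95% range -0.58 to 0.38), and it was 0.72 under TMM scaling. Random lists matched on expression had a median of -1.17, and the HOX list stood at percentile 99.35 of them.

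**Figure D3:**
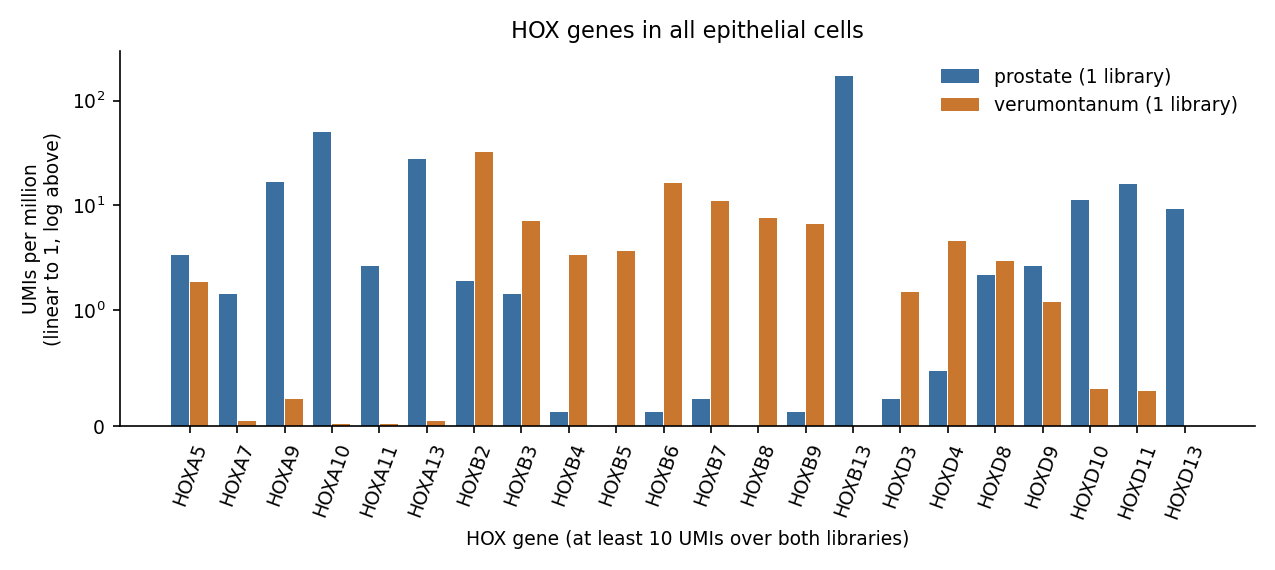
Level (CPM, y axis, linear up to 1 and logarithmic above) of the 22 HOX genes measured (x axis, in cluster and paralogue order) in all epithelial cells, with 1 bar per library and no error bars. The prostate bar is the taller in groups 10 to 13, and the verumontanum bar from HOXB2 to HOXB9.

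UMIs of epithelial genes were seen in droplets of other classes, read here as free RNA from broken cells, which was not tested. A KLK3 UMI was seen in 89.9% of luminal-like cells (median 3316 UMIs) and in 22.0% of prostate endothelial-like cells (median 8693 UMIs), which should lack it; after thinning to 1000 UMIs the endothelial share was 2.82%. KRT13 was seen in 93.1% of verumontanum epithelial cells (median 17127 UMIs; 65.8% thinned) and in 7.85% of endothelial-like cells (median 6282.5 UMIs; 1.76% thinned). Epithelial genes were therefore not read as expression of other classes, where the stratified squamous list also stood higher in verumontanum. Its medians were 3.69 in endothelial-like, 3.68 in mural-like, 2.31 in fibroblast-like and 2.08 in myeloid-like cells, on 4, 3, 5 and 5 members. The list also holds S100A9, a myeloid marker here, so its myeloid-like median need not come from free RNA alone.

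The basal-like cells of the libraries formed separate clusters with different keratins, so ratios within this class may compare different cell types. The hillock marker KRT13 measured 96.2 CPM in the prostate library and 2015 CPM in the verumontanum library. KRT14, a keratin of basal layers (ENSG00000186847, chromosome 17, 41582279 to 41586921), measured 696 (649.7 to 745) CPM in the prostate library and 0.6 (0.22 to 1.31) CPM in the verumontanum library. KRT15 stood at 1652 and 59.1 CPM, KRT5 at 1462 and 194 CPM and the basal transcription factor gene TP63 at 22.4 and 1.2 CPM. KRT17 (3771 and 6866 CPM) and the laminin gene LAMB3 (401 and 621 CPM) differed by less than 2-fold. The matrix gene TNC had a ratio of 0.000511 (0.0000129 to 0.00288) on 1 verumontanum UMI. Higher in verumontanum were CCL20 (6.64 and 4804 CPM), MMP1 (0 UMIs and 1328 (1305 to 1350.3) CPM, at least 533-fold), IL1A (at least 432-fold) and AKR1C2, with a ratio of 3727 (669 to 147230.0) on 1 prostate UMI.

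Of 12 basal epithelial genes, 7 were at least 2-fold lower in verumontanum basal-like cells, 0 higher and 5 between, with a median of -1.82 (95% range -2.15 to -1.49). All 7 MHC class II genes, which present antigen, were lower, with a median of -2.51 (95% range -2.99 to -2.07); CD74 measured 324 and 36.4 CPM. Among 19 immediate early genes, which respond to stimulation within minutes, 13 were lower, 0 higher and 6 between, median -2.12 (95% range -2.17 to -2.03), with EGR1 at 541 and 6.7 CPM and JUN at 2438 and 139 CPM. The MHC class II median was -0.30 when each cell counted equally (means of per-cell CPM). The 7 metallothioneins measured were all lower, median -5.17 (95% range -6.55 to -4.41). Androgen-regulated genes were 17 lower, 2 higher and 4 between of 23, median -2.63 (95% range -2.89 to -2.43), with KLK3 at 531 CPM in prostate basal-like cells, against 60.2 CPM in prostate T or NK-like cells, which should lack it; the median was -1.42 with means of per-cell CPM. Lists of other cell types also stood lower in these cells: 9 of 11 smooth muscle contractile genes (median -2.75 (95% range -2.99 to -2.57)), 10 of 14 extracellular matrix genes (-3.39 (95% range -3.80 to -2.77)) and 12 of 17 club genes (-2.03 (95% range -2.67 to -1.63)). The haemoglobin gene HBB of red cells had a ratio of 0.000791 (0.0000953 to 0.00288) on 2 verumontanum UMIs. All 115 prostate basal-like cells lay in cluster 19, with 5 of verumontanum, and those of verumontanum almost all cluster 2 (606 cells, 0 from prostate), with median depths of 1337 and 13662 UMIs. The basal list median was -0.59 with means of per-cell CPM, -0.75 with a mitochondrial limit of 10%, -1.15 after thinning and -2.84 at clustering resolution 0.5; the median of all genes was -0.26, and TMM scaling added 0.69.

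In endothelial-like cells of verumontanum, 10 of 15 inflammatory genes induced by NF-kB were at least 2-fold higher, 0 lower and 5 between, with a median of 1.51 (95% range 1.42 to 1.53), above every one of 10000 random lists matched on expression. The cytokine IL6 measured 1074 (1050.2 to 1098) CPM in the prostate library and 4882 (4827 to 4938) CPM in the verumontanum library. The chemokines CXCL8 and CXCL1 stood at 2364 and 9943 CPM and at 397 and 1535 CPM. Verumontanum epithelium held IL6 at 5.44 CPM and CXCL8 at 3488 CPM, and club genes stood higher in endothelial-like cells too, 6 of 9 with a median of 2.22 (95% range 1.71 to 3.42). F3, tissue factor, which starts coagulation, was 20.4-fold higher (3.41 and 69.7 CPM), the fatty acid carrier FABP5 12.2-fold (47.3 and 579.6 CPM) and the stress gene TRIB3 11.3-fold (17.7 and 201 CPM).

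Lower in verumontanum endothelial-like cells were the growth factor gene TGFB2 (82.3 and 4.23 CPM, 19.5-fold) and the adhesion gene CEACAM1 (114 and 11.1 CPM, 10.3-fold), and NOX5, a calcium-activated oxidase, had a ratio of 0.017 (0.00204 to 0.0626) on 2 verumontanum UMIs. Of 10 artery and capillary genes, 6 were lower, 2 higher and 2 between, with a median of -1.27 (95% range -1.41 to -1.16); the gap junction gene GJA5 stood at 13.6 and 1.95 CPM, RGCC at 462 and 123 CPM and CD36 at 7.37 and 35.6 CPM. All 8 vein and activation genes lay within 2-fold, median 0.24 (95% range 0.18 to 0.30). HOX genes were 11 lower, 0 higher and 6 between of 17, median -1.22 (95% range -1.59 to -1.07), and heat shock genes 7 lower, 0 higher and 7 between of 14, median -0.98 (95% range -1.20 to -0.77). Clusters 0, 15 and 17 held endothelial-like cells of both libraries, cluster 11 was mostly prostate (191 and 5 cells) and cluster 20 mostly verumontanum (1 and 117 cells). The median of all genes was -0.15, and TMM scaling added 0.27.

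In mural-like cells of verumontanum, 6 of 16 smooth muscle contractile genes were at least 2-fold lower, 0 higher and 10 between, with a median of -0.78 (95% range -0.86 to -0.75), which was -0.17 with a mitochondrial limit of 10%. The smooth muscle actin ACTG2 measured 1381 (1344 to 1419.8) CPM in the prostate library and 358 (335 to 382) CPM in the verumontanum library, desmin (DES) 1919 and 540.3 CPM and the kinase MYLK 1019.6 and 369 CPM, while TAGLN, at 9052 and 9513 CPM, was close to equal. PCP4, a calmodulin regulator, was 12.3-fold lower (597 and 48.7 CPM). TAC1, which encodes the neuropeptide substance P, was 25.4-fold higher (5.13 and 130.5 CPM), and CALCA, which encodes calcitonin gene-related peptide, stood at 17.6 and 107 CPM.

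The heat shock chaperone gene HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946), which shares nearly all of its sequence with HSPA1B, was 21.4-fold lower in verumontanum mural-like cells (5534 and 259 CPM). Of 14 heat shock genes there, 8 were lower, 0 higher and 6 between, median -1.93 (95% range -2.04 to -1.81). NF-kB genes were 6 higher, 1 lower and 7 between of 14, median 0.75 (95% range 0.65 to 0.83), with IL6 at 295 and 1174 CPM; the median was 0.16 in the clusters both libraries share. MHC class II genes were 3 lower and 3 between of 6, median -1.51 (95% range -2.06 to -0.93), with CD74 at 21.9 and 4.39 CPM, a prostate level close to that of KLK3 there (20.5 CPM), which mural cells should lack. That median was -0.45 with doublets kept and -2.71 in shared clusters. RNA of other cell types stood lower with it: 5 of 8 endothelial vein and activation genes (median -2.25 (95% range -2.56 to -0.92)), among them SELE at 148 and 3.19 CPM, and the haemoglobin genes HBB and HBA2 (which shares its sequence with HBA1), at least 27.5-fold and at least 31.8-fold lower. Clusters 4 and 7 held mural-like cells of both libraries, and the pericyte-like cluster 12 was mostly prostate (182 and 12 cells). Cluster 25 (25 and 9 cells, median 15.1% mitochondrial counts) had DES, ACTG2, PCP4 and MYLK among its top 10 genes; in clusters 4 and 7 alone the contractile median was -0.78. HOX genes in mural-like cells were 3 lower, 2 higher and 5 between of 10, median -0.12 (95% range -0.58 to 0.40). TMM scaling added 0.16 to mural ratios.

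Among fibroblast-like cells, SRD5A2, the reductase that makes dihydrotestosterone from testosterone (ENSG00000277893, chromosome 2, 31522480 to 31581067), stood at 88.7 (72.1 to 108) CPM in prostate with 0 UMIs in verumontanum, at least 103-fold lower. STC1, a secreted hormone of calcium and phosphate balance (ENSG00000159167, chromosome 8, 23841915 to 23854807), measured 3925 (3859 to 3991) CPM in verumontanum on 1 prostate UMI, a ratio of 4427 (794 to 174872). The Wnt inhibitor DKK1 stood at 7.09 and 572 CPM and the protease inhibitor TFPI2 at 31 and 643 CPM, while the opioid peptide gene PENK (103 and 5.75 CPM), PAGE4 (482 and 38.2 CPM) and the homeobox gene ISL1 (59.4 and 1.44 CPM) were lower in verumontanum.

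Of 14 steroid receptors and enzymes, 7 were at least 2-fold lower, 2 higher and 5 between, with a median of -1.02 (95% range -1.58 to -0.49), which was -1.95 for members with at least 50 UMIs and -0.27 in the cluster both libraries share. The oestrogen receptor gene ESR1 measured 53.2 and 3.45 CPM, the progesterone receptor gene PGR 40.8 and 4.03 CPM and the cortisol-activating enzyme gene HSD11B1 202 and 26.7 CPM. Of 7 HOX genes measured, 6 were lower and 1 was higher, median -3.07 (95% range -3.47 to -2.16), with HOXA11 at 35.5 and 2.3 CPM and HOXA10 at 42.6 and 4.89 CPM. The NF-kB genes were 12 higher, 0 lower and 3 between of 15, median 2.18 (95% range 1.40 to 2.40), including CXCL1 (45.2 and 579 CPM) and CXCL8 (350.2 and 2829 CPM). Genes of epithelial lists stood higher in the same cells: 5 of 9 club genes (median 1.37 (95% range 0.77 to 1.60)), 3 of 5 stratified squamous genes and the keratin KRT18 (6.21 and 303 CPM). The club list also holds C3, a fibroblast marker here. KRT13 stood at 22.4 CPM in verumontanum fibroblast-like cells, against 1331 to 2015 CPM in the epithelial classes there. CXCL8 stood at 3488 CPM in verumontanum epithelium. Extracellular matrix genes were 8 lower, 2 higher and 16 between of 26, median -0.69 (95% range -0.75 to -0.56), with the collagen COL1A1 at 365 and 119 CPM. Metallothioneins were 4 higher and 3 between of 7, median 1.28 (95% range 0.55 to 1.69), with MT2A at 4599.5 and 21559 CPM. MHC class II genes were 4 higher and 1 between of 5, median 1.24 (95% range 0.81 to 1.82) (0.30 after thinning to 1000 UMIs), and heat shock genes 10 lower and 4 between of 14, median -1.65 (95% range -1.75 to -1.58).

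Of verumontanum fibroblast-like cells, 324 lay in cluster 6, with 1 prostate cell, and cluster 22 held 48 prostate cells and 0 from verumontanum. In cluster 10, with 57 prostate and 140 verumontanum cells, the HOX median was -1.12, the NF-kB median 1.26 and the heat shock median -0.83, and ANGPTL7, a secreted angiopoietin-like protein at 106 and 6.61 CPM in the whole class, had a log2 ratio of 1.37, the reverse of its direction over the class. The median of all genes in fibroblast-like cells was -0.26, and TMM scaling added 0.46.

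Immune cells of verumontanum held less heat shock RNA. In T or NK-like cells all 14 heat shock genes were at least 2-fold lower, with a median of -2.58 (95% range -2.72 to -2.35); HSP90AA1 measured 10051 (9647 to 10467) CPM in the prostate library and 1499 (1386 to 1619) CPM in the verumontanum library, and HSPA6, a strictly inducible chaperone gene, 1540.3 and 113 CPM. In myeloid-like cells 12 of 14 were lower and 2 lay between, median -2.94 (95% range -3.13 to -2.83), with the mitochondrial chaperone HSPD1 at 2712 and 159 CPM. In T or NK-like cells the lymphocyte receptor CD7 was 4.48-fold higher in verumontanum (275 and 1234 CPM). The NK receptor KLRC1 (86.1 and 371 CPM) and the checkpoint receptor PDCD1 (25.8 and 138 CPM) were higher too. The class pools T and NK cells, with 83 cells in prostate and 264 in verumontanum. These ratios may follow the mix of the types, which was not measured.

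In verumontanum myeloid-like cells HMOX1, which breaks down haem, was 10.9-fold higher (359.9 and 3922 CPM), the chemokine CXCL1, close in sequence to CXCL2 and CXCL3, 13.5-fold (70.1 and 943 CPM) and CYP1B1 13.2-fold (51.4 and 678 CPM). CXCL9, a chemokine induced by interferon gamma, stood at 140.2 (116 to 168) CPM in prostate with 0 UMIs in verumontanum, at least 34.7-fold lower. NF-kB genes in myeloid-like cells were 10 higher, 0 lower and 5 between of 15, median 1.34 (95% range 1.28 to 1.45), with CCL20 at 906 and 4842 CPM; in T or NK-like cells 1 was higher, 2 lower and 4 between of 7, median -0.49 (95% range -0.95 to -0.11). Interferon response genes in myeloid-like cells were 7 lower, 1 higher and 6 between of 14, median -0.53 (95% range -1.10 to -0.01), at percentile 3.29 of matched random lists and from -1.07 to -0.33 over the settings, and metallothioneins 4 lower, 1 higher and 3 between of 8, median -1.07 (95% range -2.27 to -0.50). T or NK-like cells were cluster 5 and myeloid-like cells cluster 13 in both libraries; the median of all genes was 0.07 and 0.10.

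**Figure D4:**
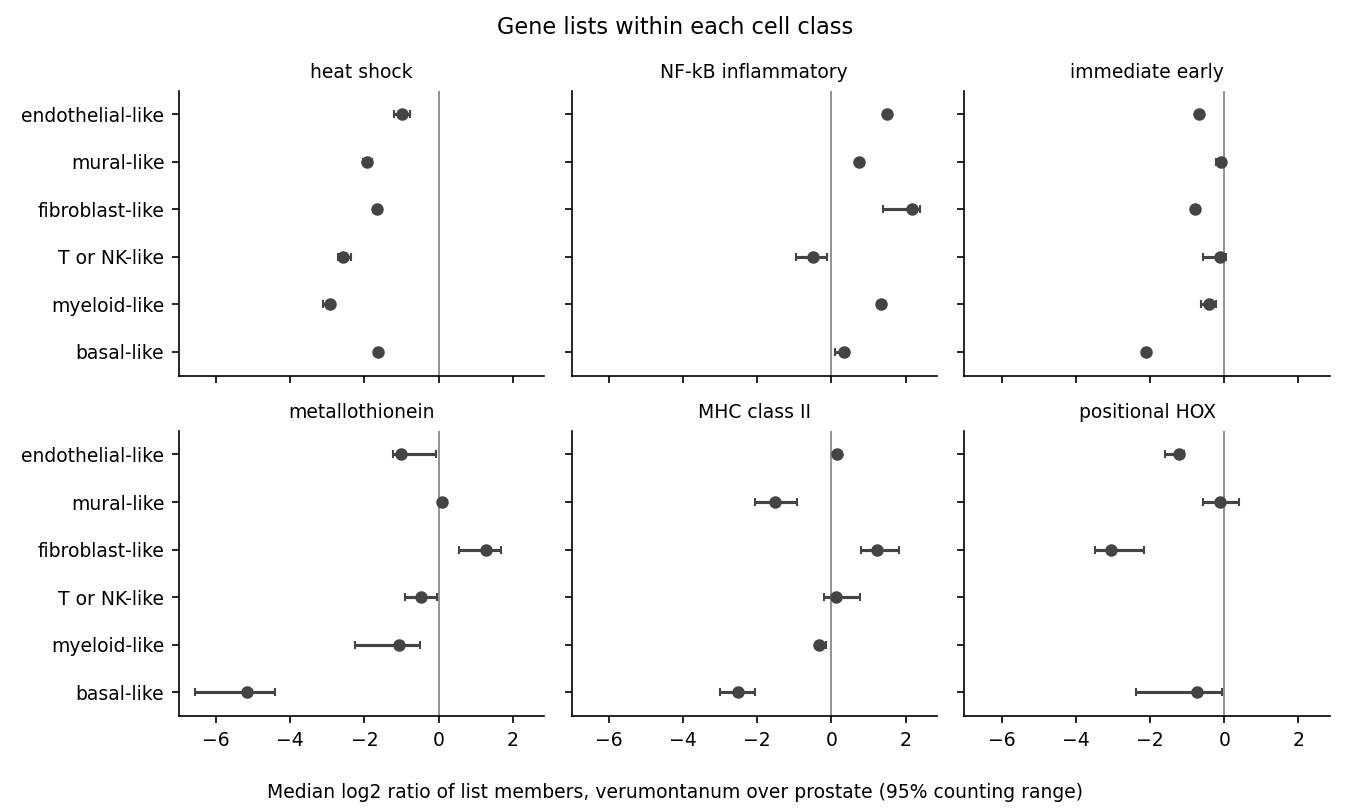
Median log2 ratio of verumontanum over prostate (x axis) in each of 6 cell classes (y axis), with 1 panel per gene list and bars for the 95% counting range of the median. Heat shock medians lie below 0 in all the classes drawn, from -0.98 in endothelial-like to -2.94 in myeloid-like cells.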

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

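The median log2 ratio of the MHC class II list was 3.75 higher in fibroblast-like than in basal-like cells, flagged because its members stood higher in verumontanum in the first class and lower in the second. The difference between the classes was not tested, and the medians behind it depended on settings, with -0.30 in basal-like cells under per-cell means and 0.30 in fibroblast-like cells after thinning. The metallothionein list was flagged in the same way, with a median 6.45 higher in fibroblast-like than in basal-like cells, and this difference was not tested either.

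SCGB1A1, a secretory gene of club cells, was flagged as a signal in barcodes that the comparisons leave out: it stood at 65.9 CPM in the left-out prostate barcodes, where a count of 0 would allow 0.734 CPM, against 2.83 CPM in kept cells. Of its 269 UMIs there, 268 came from 1 barcode with 25.7% of counts from mitochondrial genes. HBA2, a haemoglobin gene that shares its sequence with HBA1, was flagged in the same barcodes at 844 CPM, against 98.0 CPM in kept cells, with 2096 of its 3449 UMIs in 1 barcode.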

How the results depend on the processing

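No paired analysis was possible because each region had 1 library and the labels pair none. Leaving out the results given setting by setting below, the named genes took 1274 values under the alternatives, of which 1022 stayed within their interval, 251 moved beyond it and 1 reversed. For the list medians these counts were 346, 132 and 1 of 479 values, and for the shares 172, 48 and 0 of 220. These counts include the last 2 reversals named below, and a list counts as reversed only if its main 95% range leaves out 0, so sign changes of the epithelial HOX median (-0.20; -0.85 to 1.38 over settings) are among the moves. All 140 named genes kept their direction with no filter, with doublets kept and with per-cell means. The cause of the moves below was not tested, except that TMM and DESeq2 add 1 constant per class by construction. The androgen-regulated median in luminal-like cells was not run, since no setting gave 30 such cells in verumontanum. The HOX median in fibroblast-like cells was not run with thinning or a minimum of 50 UMIs, for which too few members remained. With at least 500 genes the basal-like class had under 30 cells in a library and was not compared, and 28 of 35 list medians were run. The doublet score of 0.25, the rule of 3 markers and the shared clusters were chosen after seeing the data.

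The prostate epithelial share (18.4%) was 16.6% with a 10% mitochondrial limit and 14.5% with at least 500 genes. The verumontanum epithelial share (46.2%) was 27.2% with a 10% mitochondrial limit, 40.7% with no filter and 25.0% with separate clustering. The verumontanum club- and hillock-like share of epithelial cells (0) was 47.6% with a 10% mitochondrial limit, 41.4% with no filter, 31.7% with at least 500 genes, 17.8% at resolution 2, 30.2% with separate clustering and 19.6% with 3 markers. The club median in epithelium (0.41) reversed to -0.51 with members of at least 1 UMI, and was 2.33 with a 10% mitochondrial limit, 1.33 with TMM, 1.37 with DESeq2, 0.61 without mitochondrial and ribosomal protein genes, 1.04 with per-cell means, 2.74 thinned and 0.56 with at least 50 UMIs.

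The basal median in basal-like cells (-1.82) was -0.75 with a 10% mitochondrial limit, -2.84 at resolution 0.5, -1.13 with TMM, -1.09 with DESeq2, -0.59 with per-cell means and -1.15 thinned. The endothelial NF-kB median (1.51) was 1.42 with 4000 variable genes, 1.78 with TMM, 1.83 with DESeq2, 1.57 without mitochondrial and ribosomal protein genes, 1.82 with per-cell means, 1.72 thinned and 1.39 in shared clusters. The mural contractile median (-0.78) was -0.17 with a 10% mitochondrial limit, -0.93 with no filter, -0.62 with TMM, -0.58 with DESeq2, -0.63 with per-cell means and -0.64 thinned. The heat shock median in T or NK-like cells (-2.58) was -2.31 with per-cell means and -2.30 thinned, and in myeloid-like cells (-2.94) it was -3.21 with no filter, -2.67 with at least 500 genes and -2.65 with doublets kept. The HOX median in fibroblast-like cells (-3.07) was -1.62 with members of at least 1 UMI and -1.12 in the shared cluster. The NF-kB median in basal-like cells (0.35) reversed to -0.37 at resolution 0.5, and ANGPTL7 in fibroblast-like cells to 1.37 in the shared cluster. Other list medians that moved by over 1.5 times ran, over all settings, from -2.87 to -0.30 (MHC class II, basal-like), -2.71 to -0.45 (mural-like) and 0.30 to 1.73 (fibroblast-like). NF-kB ran from -1.32 to -0.07 (T or NK-like), 1.26 to 2.68 (fibroblast-like) and 0.16 to 1.18 (mural-like), androgen-regulated genes from -5.63 to -4.47 (epithelium) and -3.16 to -1.42 (basal-like), and steroid genes from -1.95 to -0.27. Heat shock ran from -1.66 to -0.69 (basal-like) and -1.80 to -0.83 (fibroblast-like), immediate early genes from -2.19 to -1.39, metallothioneins from -7.68 to -6.09 (epithelium), -7.28 to -4.18 (basal-like) and 1.17 to 1.92 (fibroblast-like), fluid proteins from -10.19 to -8.14 and squamous genes from 2.06 to 4.04.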

Other observations

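Zinc transporters, the carriers that fill prostatic secretion and cells with zinc, were 11 lower, 1 higher and 3 between of 15 in verumontanum epithelium, with a median log2 ratio of -1.97 (95% range -2.10 to -1.83). SLC30A4 stood at 262 and 0.279 CPM in prostate and verumontanum, SLC39A10 at 181 and 18.7 CPM, and SLC39A4 was higher at 8.71 and 34.6 CPM. Polyamine genes, whose products are rich in prostatic fluid, were 4 higher, 4 lower and 2 between of 10, median 0.43 (95% range 0.25 to 0.65), with ODC1, which opens polyamine synthesis, at 361 and 752 CPM and the spermine synthase gene SMS at 366 and 57.8 CPM. Oxidative phosphorylation genes, which make ATP in mitochondria, were 2 higher and 22 between of 24, median 0.39 (95% range 0.36 to 0.41). MHC class I genes were 4 lower and 7 between of 11, median -0.79 (95% range -0.89 to -0.58), with HLA-B at 1019 and 429.9 CPM, and cell cycle genes 7 lower and 8 between of 15, median -0.97 (95% range -1.53 to -0.49). Neither stood apart from random lists matched on expression, whose medians were -0.43 and -1.32, at percentiles of 23.0 and 72.4. Oxidative phosphorylation (87.7) and polyamine genes (93.6) did not either, while zinc transporters were at 0.110. Within basal-like cells zinc transporters were 5 lower, 1 higher and 9 between of 15, median -0.44, at percentile 63.8.

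Signalling ligands and antagonists of development in fibroblast-like cells were 13 lower, 6 higher and 10 between of 29, median -0.19 (95% range -0.66 to 0.20), at percentile 58.2 of matched random lists. The hedgehog targets PTCH1 and GLI1 stood at 36.3 and 4.6 CPM and at 16.8 and 1.44 CPM, the Wnt inhibitor SFRP4 at 501 and 90 CPM, and the activin antagonist FST at 39.9 and 189 CPM. Complement genes in endothelial-like cells were 4 higher and 6 between of 10, median 0.82 (95% range 0.58 to 0.99). In whole libraries, before any filter, the neuroendocrine gene CHGA had 8 UMIs in prostate and 0 in verumontanum, which allows up to 0.0450 CPM.

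All tests of the 3 patterns below were chosen after the results were seen. The near absence of prostate secretory RNA in verumontanum was weighed first. If the filter had removed secretory cells, their RNA should stand in all deposited barcodes, but the upper 95% bound of KLK3 there was 0.00209% of the prostate level, which excludes this explanation for KLK3. Sampling of urethral lining with few glands could leave the same picture as a difference of region: luminal-like cells were 0.0501% of verumontanum epithelial cells, and 1 library per region cannot tell these apart.

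Lower heat shock RNA in verumontanum was weighed second. Free RNA was scaled by KLK3 and taken to have the make-up of all deposited prostate barcodes. It gave at most 0.860% of the heat shock CPM in the 5 non-epithelial classes of prostate. Free RNA of that make-up was too little to account for the pattern there. Free RNA poor in KLK3, from cells other than luminal-like ones, was not covered. Basal-like cells, with KLK3 at 531 CPM, were not run. Different clusters holding a class did not account for all of it in endothelial-, mural- and fibroblast-like cells, where the highest median in shared clusters was -0.77. A part was not excluded: the fibroblast-like median was -1.65 in the class and -0.83 in its shared cluster. Basal-like cells had no cluster with at least 30 cells of each library, so this could not be run there. The highest of the 6 class medians was -0.98, so every class stood lower. Handling of the tissue pieces, whose warming or digestion could induce these genes, would give this, but with 1 library per region the design cannot tell handling, donor and region apart.

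Lower HOX RNA in verumontanum fibroblast-like cells was weighed last. Counting error alone was excluded as the source of the lower values in the class, since 6 of 7 members had an interval below 1, although only 1 reached 50 UMIs and the median was -1.62 with members of at least 1 UMI. In the cluster that both libraries share the median was -1.12 (95% range -2.27 to -0.22 over 5 members, 2 of them with an interval below 1), nearer to 0 than in the class, and with a TMM shift of 0.46 this cannot tell a difference in fibroblast subtypes from one within a subtype. Region itself was not tested in any of these patterns, since no second library of either region exists here.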
